A study of Mus musculus with 6 samples.

How the data were processed

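RNA was profiled from keratinocytes of the skin of mice carrying a transgene in which a keratin 15 (K15) promoter drives enhanced green fluorescent protein (EGFP). Cells were separated by flow cytometry on EGFP and on surface α6 integrin, the product of Itga6, which basal keratinocytes hold at their contact with the basement membrane. The labels give 6 arrays in 2 groups of 3. EGFP-high cells and EGFP-negative cells were both α6 integrin positive. Each sample takes its group and its replicate number from its own title. The labels do not say whether the replicates came from separate animals or sorts, so p-values measure the spread between these samples, part of which may be technical.

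The authors deposited 1 intensity per probe set and array on a linear scale, for an Affymetrix mouse array of 12488 rows. The values are not log transformed and not centred by gene. In each of the 6 columns the mean after trimming 2% at each end was 150.0, so the arrays had been scaled to a common level before deposit. The software, background method and any filter behind these values are not given in the sources used here. Array medians lay between 69.75 and 76.2, the largest being 1.09 times the smallest. This was under the limit of 1.2 fixed for rescaling, so the deposited scale was kept. The number of arrays limits the precision, and no read depth applies.

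The 66 control rows were left out of all tests. Of the other 12422 probe sets, 10833 paired with 1 gene symbol, 396 with several and 1193 with no listed gene in the platform annotation. Symbols were looked up through Entrez gene identifiers in a RefSeq gene table of the GRCm38.p6 assembly, used for names only. The lookup matched 10817 probe sets and changed 0 symbols. The other 16 kept the annotated symbol. No probe set with several symbols was given a name.

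Intensities were analysed as log2(value + 19.3), where 19.3 is the 25th percentile of all deposited values above 0. A fold change is on this scale, which understates the change of genes near the background. Probe sets with a mean log2 value above the 40th percentile were tested, a level near an intensity of 44.5, which kept 7453 probe sets and 5628 named genes. The EGFP-high minus EGFP-negative difference was tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. The fit had 4 residual and 4.96 prior degrees of freedom. The replicate number was not a term of the fit.

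The replicate numbers were then checked for pairing. Deviations from the group means correlated at 0.336, 0.368 and 0.305 across probe sets between the EGFP-high and EGFP-negative arrays of numbers 1, 2 and 3, and at -0.0629 or below between arrays of different number and group. Deviations cancel within a group, so negative values between different numbers follow from positive ones within numbers and are not separate support. All 3 same-number pairs were above 0.1, the limit set for this check, so the numbers were taken to pair the samples. The pairing comes from the titles and from this correlation, because the labels do not state it. The p-values, list tests and fits with arrays left out are from the fit without this pairing unless stated, as planned beforehand. Values from a fit with the replicate number as a block are printed where they changed a call or moved a count by more than 1.5 times.

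A gene was represented by its probe set with the highest mean log2 value. Before the data were examined, 33 gene lists were fixed from general knowledge: 20 pathway and compartment lists and 13 lists of markers of cell types the gates could hold. The pathway and compartment lists were bulge stem cell markers, basal keratinocyte genes, epidermal differentiation genes, infundibulum and isthmus genes, sebaceous gland genes, hair matrix and shaft genes, cell cycle genes, cell cycle inhibitors and quiescence genes, Wnt pathway genes, TGF-beta and BMP pathway genes, FGF, Hedgehog and Notch pathway genes, basement membrane, matrix and integrin genes, actin cytoskeleton and contractility genes, antigen presentation genes, immediate early and heat shock genes, detoxification and oxidative stress genes, sterol synthesis genes, glycolysis genes, oxidative phosphorylation genes and ribosomal protein genes. The marker lists covered melanocytes, T cells, Langerhans cells and macrophages, leukocytes, fibroblasts, dermal papilla, endothelial cells, Schwann cells, Merkel cells, muscle, adipocytes, erythrocytes and simple epithelium. The 27 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27. Camera with a correlation estimated from the residuals, and fry, were run beside it. Fry asks whether a list's genes move, on balance, in 1 direction and does not compare them with other genes.

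The genes named were also chosen by a rule fixed in advance. It took the genes of the sort and of the basal layer (Krt15, Itga6, Cd34, Krt14 and Krt5), then the 10 largest positive and 10 largest negative differences among the named probe sets past the threshold whose groups did not overlap. For each list it took up to 4 members past the threshold per direction with the smallest p, or the 2 brightest members where none passed. Any gene named outside this rule is said to be chosen after its values were seen.

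The analysis was tested on simulated data, drawn once per size of change, with 200 of the 7453 probe sets changed. Each probe set was given its moderated variance from limma, which is pulled toward the intensity trend. The simulated spread may therefore be more even than that of the data, and the recovery may be overstated. At a log2 change of 1 the test recovered 75.5% of the changed probe sets, with 14 false calls among 165. At a log2 change of 2 it recovered 99% with 5 false calls among 203, and at 0.5 it recovered 0.5%. In 20 simulations with the cell cycle list shifted by -0.5, camera called that list in 20, and called other lists in 5 of 520 tests. With an estimated correlation it called the shifted list in 19 and other lists in 0. All simulated genes were drawn independently and without pairing, whereas the estimated correlation of the cell cycle list in the data was 0.132. The simulated rates therefore do not describe lists of correlated genes.

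The alternatives fixed in advance were a pseudocount 25% and 4 times as large, a floor in place of a pseudocount, no filter, a stricter filter at the 60th percentile, quantile normalization, centring on the 75th percentile, eBayes without the trend or with robust estimation, array weights, the replicate block, leaving out each array in turn, camera with an estimated correlation, the mean of all probe sets of a gene, fry, and Welch's test as a count only. Leaving out both arrays of number 1 together, and the block with an estimated correlation, were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.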

Results

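Gene expression was measured in 3 samples of EGFP-high and 3 samples of EGFP-negative keratinocytes sorted from the skin of K15-EGFP mice, with 1 array per sample. In these mice the keratin 15 promoter marks cells of the hair follicle bulge, the niche of the follicle stem cells, and both gates held α6 integrin positive cells. The comparison asks which genes distinguish the bulge-enriched cells from the other basal keratinocytes. Array profiles correlated at 0.922 to 0.948 within a group and at 0.839 to 0.905 between groups, across tested probe sets on the log2 scale, and no 2 columns held identical values. Component 1 of a principal component analysis held 49.5% of the variance and separated the groups. Its scores were -10.05, -29.46 and -24.28 for EGFP-high replicates 1, 2 and 3, and 29.09, 15.98 and 18.73 for EGFP-negative replicates 1, 2 and 3. The array of EGFP-high replicate 1 stood nearest to the other group on this component.

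**Figure D1:**
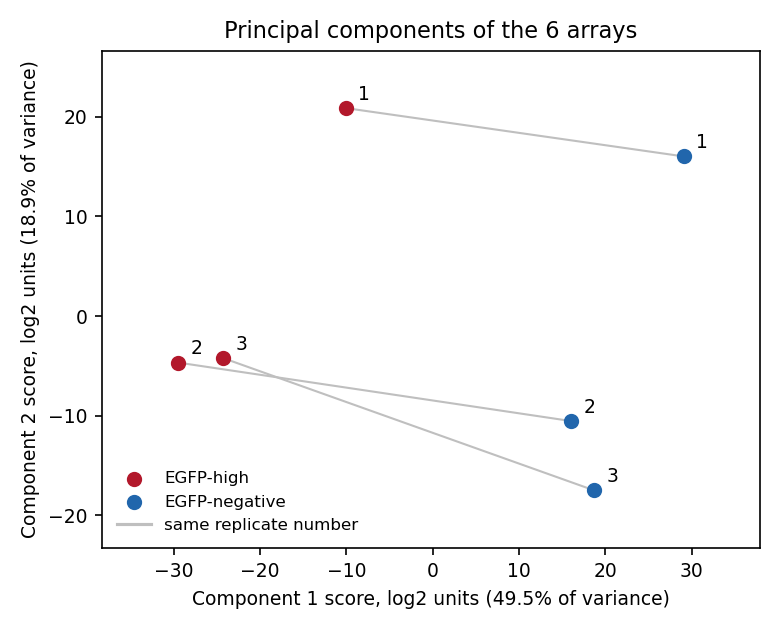
Scores of the 6 arrays on components 1 and 2 of the log2 values of all tested probe sets, in log2 units, coloured by group, with grey lines joining arrays of the same replicate number. The groups separate on component 1 (49.5% of the variance), and both arrays of number 1 lie at positive scores on component 2 (18.9%).

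Among named genes, S100a4, a calcium-binding protein, and Cd34, a surface marker of mouse bulge cells, had the largest log2 differences between EGFP-high and EGFP-negative keratinocytes on the scale used here. Cd34 read 1456 ± 120.2 in EGFP-high against 34.9 ± 5.77 in EGFP-negative cells (mean ± SD, n = 3 each). With a pseudocount 25% as large the order changed, to log2 5.50 for Cck, 5.21 for Cd34 and 5.09 for S100a4. By camera 3 of 27 gene lists were higher (bulge markers, matrix genes, and TGF-beta and BMP genes) and 4 lower (cell cycle, antigen presentation, epidermal differentiation, and ribosomal protein genes, the last not after quantile normalization), and 0 of the 7 passed with an estimated correlation. The bulge list shares called members with the matrix list and with the TGF-beta and BMP list, so the 3 higher lists are not separate results. In all, 387 of 7453 probe sets passed the threshold (limma, Benjamini-Hochberg), 225 higher and 162 lower in EGFP-high, and 283 of them differed at least 2-fold (169 higher, 114 lower). These represent 172 genes that were higher and 128 that were lower, each counted by its brightest probe set. All 387 had non-overlapping groups and the same direction in all 3 pairs. Among all tested probe sets 1695 (22.7%) did not overlap, where chance gives 10% for arrays without pairing; the share under the pairing described in the methods was not computed. With the replicate number as a block, 778 probe sets passed (382 higher, 396 lower), including all 387. Without EGFP-high replicate 3 the count fell to 191 (108 higher, 83 lower), without EGFP-high replicate 2 to 226 (135 higher, 91 lower), and without EGFP-negative replicate 3 those lower came to 99. Those at least 2-fold came to 182 without EGFP-high replicate 3. Leaving out both arrays of number 1, a choice made after seeing the data, gave 426.

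The genes of the sort and of the basal layer were read as a check of the labels. Cd34 had a log2 difference of 4.77 (SE 0.16, adjusted p = 1.04e-06), and its other probe set read 1250 against 37.1, a log2 difference of 4.49. In EGFP-negative cells Cd34 was near the upper range of the control probe sets, so the size of its rise depends on the pseudocount (log2 3.77 to 5.39 over the alternatives for low values). Itga6, the gene of the α6 integrin used in both gates, was lower in EGFP-high at 492 ± 90 against 1199.8 ± 162 (log2 -1.26, SE 0.18, adjusted p = 0.00449). The probe sets of Krt15, Krt14 and Krt5 lay at the level of the control probe sets, except Krt5 on EGFP-high replicate 2. There Krt5 read 48.9, above the control 95th percentile of 34.5 on that array. Krt15 is the gene whose promoter drives EGFP, and Krt14 and Krt5 are the main keratins of basal cells. Krt15 read 1.7 to 7.4, Krt14 6.8 to 22.2 and Krt5 10 to 48.9, where the control probe sets had medians of 9.6 to 16.5 and 95th percentiles of 25.5 to 42.3. The log2 differences given for Grem1, Dlx3, Fgf18, Fgf1, Gli2, Myl9 and Gfra1, which were at or near that level in EGFP-negative cells, and for Aurkb and Wnt3a, which were so in EGFP-high cells, likewise depend on the pseudocount. Krt15, Krt14 and Krt5 were not tested, so the arrays offer no check of the sort through Krt15 itself.

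The genes with the largest positive differences were taken among named probe sets only. S100a4 rose from 144 ± 18.2 to 5009.8 ± 131 (log2 4.95, SE 0.15, adjusted p = 8.69e-07). Cck, which encodes the peptide hormone cholecystokinin, read 568 ± 255 against 7.03 ± 1.07 (log2 4.39, SE 0.29). Lgr5, a Wnt-associated receptor of follicle stem cells, read 319.9 ± 75.5 against 5.13 ± 0.839 (log2 3.77, SE 0.21). In EGFP-negative cells Cck and Lgr5 were at the level of the control probe sets, so their folds depend on the pseudocount. Kcnk2, a potassium channel, rose by a log2 value of 3.40 (SE 0.20), and Id2, an inhibitor of basic helix-loop-helix factors, by 3.17 (SE 0.55, adjusted p = 0.0106). Krt6a, a keratin of the follicle's companion layer and of activated epidermis, reached 3323 ± 721 against 351 ± 32.4 (log2 3.15, SE 0.19). Plpp1, a lipid phosphate phosphatase, Ccn2, a matrix-associated growth factor, and Grem1, a secreted BMP antagonist, rose by log2 values of 2.98, 2.94 and 2.94. The probe set of Plpp1 is of a type that can share signal with related transcripts, so its value is less certain. Id2 lost its call without EGFP-high replicate 3 (adjusted p = 0.061).

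Among named probe sets that stand for a gene, Il1r2 had the largest negative difference. Il1r2, the interleukin 1 decoy receptor, fell from 889 ± 30.9 to 114 ± 57.4 (log2 -2.86, SE 0.28, adjusted p = 0.000615). Serpinb2, a serine protease inhibitor, read 429 ± 277 against 2312 ± 202 (log2 -2.54, SE 0.35), also on a probe set that can share signal with related transcripts. Phldb2 was at the level of the control probe sets in EGFP-high at 9.87 ± 4.7 against 132 ± 20.8 (log2 -2.38, SE 0.23), so the size of its fall, and its place among the largest, depend on the pseudocount. Smoc2, a matrix protein, Ackr3, a chemokine receptor, Slc6a4, the serotonin transporter, and Klf5, a transcription factor of proliferating epithelium, fell by 2.21, 2.18, 2.14 and 2.09 on the log2 scale. Cpxm2, Wnt4 and Anln, an actin-binding protein of cytokinesis, fell by 2.17, 2.12 and 2.04. The calls of these last 3 were lost when single arrays were left out: that of Cpxm2 with 4 of the 6 arrays (adjusted p up to 0.0903, without EGFP-high replicate 3), that of Wnt4 with 3 (up to 0.0737, without EGFP-high replicate 3) and that of Anln with 4 (up to 0.0845, without EGFP-high replicate 2).

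**Figure D2:**
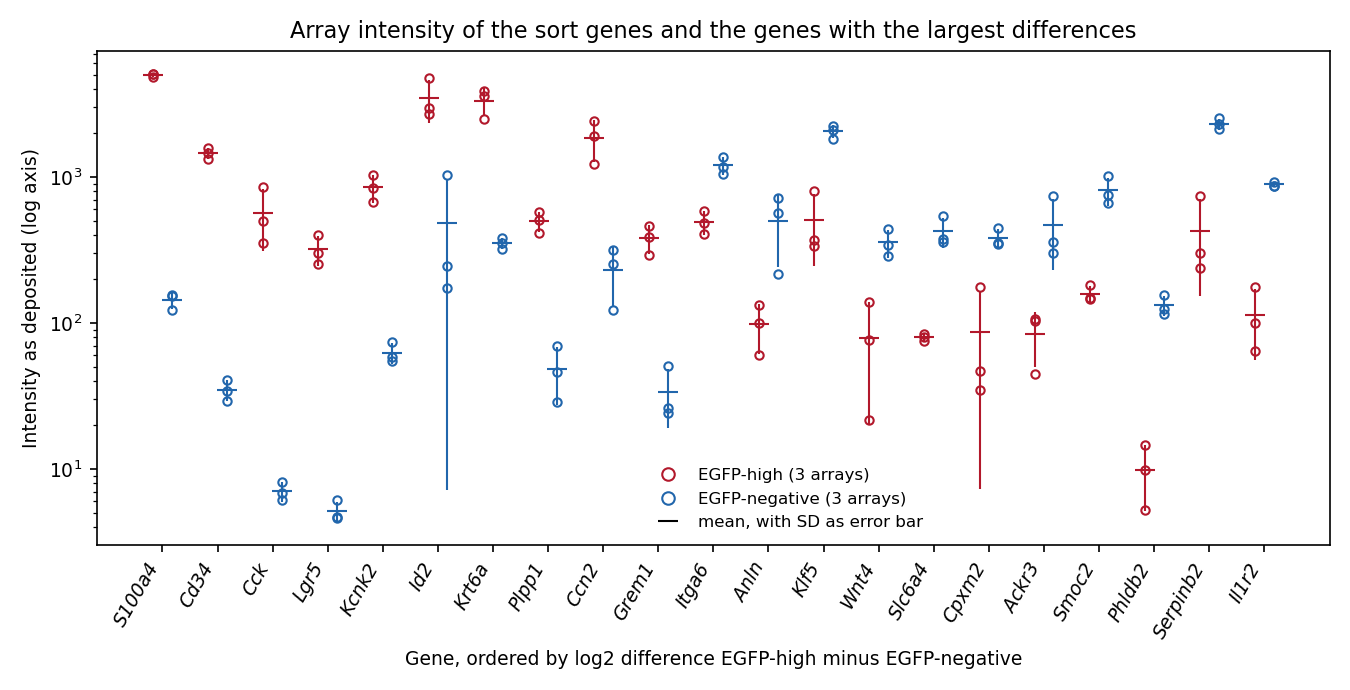
Deposited intensity (log axis) of Itga6, Cd34 and the 10 named genes with the largest positive and 10 with the largest negative log2 difference, with 3 EGFP-high arrays in red and 3 EGFP-negative arrays in blue; points are arrays, horizontal ticks are means and bars are SDs. S100a4 sits near 5010 in EGFP-high and near 144 in EGFP-negative, and the groups do not overlap in any gene shown.

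The list of known bulge markers was higher in EGFP-high cells. Of 28 tested bulge stem cell markers 19 were higher and 0 lower, with a median log2 difference of 1.73 (camera adjusted p = 3.67e-27; adjusted p = 0.276 with an estimated correlation; fry 0.00295). Adjusted over the list alone, 25 passed, 24 higher and 1 lower. The list may hold genes that were first reported from these arrays, so it is not independent evidence of direction. It also shares members with other lists. Among others, Grem1, Ccn2 and Ltbp2 are in the TGF-beta and BMP list, and Postn, Npnt and Col6a1 in the matrix list. Dkk3, Sfrp1 and Tcf7l1 are in the Wnt list, and Fgf18 in the FGF, Hedgehog and Notch list. Results for those lists are therefore not separate from this one, and they were not tested without the shared genes. Beside Cd34, S100a4 and Lgr5 the leading members were Postn, a secreted matrix protein that was among the brightest genes at 7519 ± 485 against 1324 ± 147 (log2 2.49, SE 0.15, adjusted p = 5.17e-05), and the secreted factors Dkk3 and Fgf18. Without any single array the number higher stayed between 16 and 20.

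The lists of signalling pathways held genes called in both directions. In the Wnt list 4 of 34 tested genes were higher and 3 lower, and camera gave an adjusted p of 0.534. Adjusted over the list alone 12 passed, 5 higher and 7 lower. The receptor Fzd2 (880 ± 180 against 104 ± 38.7, log2 2.89, SE 0.26), the secreted modulators Dkk3 (log2 2.49) and Sfrp1 (log2 2.36), and the transcriptional repressor Tcf7l1 (log2 1.58) rose. The ligands Wnt10a (log2 -1.69), Wnt3a (log2 -1.53) and Wnt4 (log2 -2.12) fell. In the TGF-beta and BMP list 10 of 37 genes were higher and 1 lower, with 14 passing when adjusted over the list alone and a median of 0.24 (camera adjusted p = 0.000429; adjusted p = 0.528 with an estimated correlation; fry 0.0655, not past the threshold). Those that rose included the antagonists Grem1 and Smad6 (log2 1.64), the growth factor Ccn2 and the latent TGF-beta binding protein Ltbp2 (log2 2.54), and the ligand Bmp4 fell (log2 -0.76; log2 -2.45 on its other probe set, and -1.61 for the mean of both, adjusted p = 0.00247). That other probe set read 33.9 in EGFP-high, within the range of the control probe sets, so these last 2 sizes depend on the pseudocount. In the FGF, Hedgehog and Notch list 4 of 26 genes were higher and 1 lower, 8 passed when adjusted over the list alone, and camera gave an adjusted p of 0.404 (fry 0.0298). Fgf18 (log2 2.71), Fgf1 (log2 2.21), the receptor Fgfr1 (log2 2.77) and the Hedgehog effector Gli2 (log2 1.07) rose, and the Notch ligand Dll1 fell (log2 -0.81). The probe sets of Fgfr1 and Bmp4 can share signal with related transcripts. With the block, 5 Wnt genes and 2 TGF-beta and BMP genes were lower. The TGF-beta and BMP genes higher came to 5 without EGFP-high replicate 3 and 6 without EGFP-high replicate 2, and the FGF, Hedgehog and Notch genes higher to 2 without EGFP-high replicate 3. Single arrays ended the calls of Tcf7l1, Dll1 (both up to an adjusted p of 0.147), Bmp4 (up to 0.0911), Fgfr1 (0.0577) and Wnt4 (up to 0.0737), each highest without EGFP-high replicate 3, and of Gli2 (up to 0.172, without EGFP-high replicate 2).

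The matrix list was higher in EGFP-high cells by camera. Of 42 tested basement membrane, matrix and integrin genes 10 were higher and 2 lower, 16 passed when adjusted over the list alone, and the median was 0.34 (camera adjusted p = 3.8e-05; adjusted p = 0.528 with an estimated correlation; fry 0.0441). Beside Postn, the collagen Col6a1 (1369.7 ± 269 against 296 ± 21.5, log2 2.12, SE 0.18), the integrin ligand Npnt (log2 2.50) and the metalloproteinase inhibitor Timp2 (log2 1.84) rose. Postn, Col6a1 and Npnt also belong to the bulge list. Itga6 and the matricellular protein Thbs2 (log2 -1.46) fell. The hemidesmosome partner Itgb4 read 1552 in EGFP-high and 1418 in EGFP-negative cells (adjusted p = 0.921), named here after its values were seen. In the actin cytoskeleton list 4 of 30 genes were higher and 1 lower, 7 passed when adjusted over the list alone, and camera gave an adjusted p of 0.351. Myl9, a myosin light chain (133 ± 37.7 against 10.1 ± 3.75, log2 2.35, SE 0.26), Actn1 (log2 2.21), Msn (log2 1.06) and Tpm1 (log2 0.85) rose, and Pdlim1 fell (log2 -0.98). The count of matrix genes higher came to 6 without EGFP-high replicate 3, and that of those lower to 4 without EGFP-high replicate 1 and to 1 without EGFP-high replicate 3 or EGFP-negative replicate 2 or 3. With all arrays the block gave 2 actin cytoskeleton genes lower. Single arrays ended the calls of Thbs2 (adjusted p up to 0.0743) and Tpm1 (up to 0.169), each highest without EGFP-high replicate 3, and of Pdlim1 (up to 0.0565, without EGFP-high replicate 2).

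The cell cycle list was lower in EGFP-high cells by camera. Of 59 tested cell cycle genes 0 were higher and 11 lower, with a median of -0.63 (camera adjusted p = 4.77e-12; adjusted p = 0.48 with an estimated correlation; fry 0.0298). Adjusted over the list alone, 31 passed, 30 lower and 1 higher, and with the block 26 were lower and 1 higher. Aurkb, a mitotic kinase, read 28.7 ± 4.66 against 135 ± 23.7 (log2 -1.68, SE 0.21, adjusted p = 0.00213), and the kinase subunit Cks2 102 ± 12.4 against 372 ± 123 (log2 -1.65, SE 0.25). The cytokinesis kinesin Kif23 (log2 -1.44) and the cyclin Ccnd2 (log2 -1.42) fell as well. Of 25 cell cycle inhibitors and quiescence genes 3 were higher and 1 lower, 3 were lower with the block, and camera gave an adjusted p of 0.416. Adjusted over that list alone 8 passed, 4 higher and 4 lower. Cited2, a transcriptional coregulator (1140.4 ± 219.7 against 265 ± 38.9, log2 2.02, SE 0.19), the growth-arrest gene Gas1 (2503 ± 476 against 966 ± 154, log2 1.35, SE 0.19) and the imprinted gene Peg3 (log2 0.91) rose, and the cyclin Ccng2 fell (log2 -1.29). The number of cell cycle genes lower depended on single arrays: it was 4 without EGFP-negative replicate 1 or EGFP-negative replicate 3, 5 without EGFP-high replicate 2, 7 without EGFP-high replicate 3 and 17 without EGFP-negative replicate 2. Without both arrays of number 1 it was 4. The inhibitors lower came to 2 without EGFP-high replicate 2 or EGFP-negative replicate 2 or 3. This probe set of Peg3, the brightest, lost its call without any 1 of the 6 arrays (adjusted p up to 0.146, without EGFP-high replicate 2). The other 2 Peg3 probe sets had log2 differences of 1.86 and 1.97 (adjusted p = 0.00854 and 0.00438), sizes that depend on the pseudocount because both were within the range of the control probe sets in EGFP-negative cells.

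Most genes of the basal list did not pass the threshold, and the antigen presentation list was lower in EGFP-high cells by camera. Of 17 basal keratinocyte genes 0 were higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.312): Itga6, the cell cycle regulator Sfn (1931 ± 182 against 4959 ± 1536, log2 -1.31, SE 0.23) and the desmosomal protein Pkp1 (log2 -0.90). Of 20 epidermal differentiation genes 0 were higher and 1 lower, the transcription factor Pou2f3 (log2 -0.89), with 2 passing when adjusted over the list alone and a median of -0.34 (camera adjusted p = 0.00344; adjusted p = 0.528 with an estimated correlation; fry 0.197, not past the threshold). With the block 4 differentiation genes were lower. Of 17 antigen presentation genes 0 were higher and 6 lower, also when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00201; adjusted p = 0.528 with an estimated correlation; fry 0.0219). The class I heavy chains H2-D1 (2557 ± 169.7 against 5974 ± 276, log2 -1.22, SE 0.14) and H2-K1 (3579 ± 165 against 7169 ± 279, adjusted p = 0.00352) and the immunoproteasome subunits Psmb8 (log2 -1.38) and Psmb9 (log2 -1.14) fell. Class I probe sets can share signal among related heavy chains. The differentiation genes lower came to 6 without EGFP-high replicate 1 and to 0 without EGFP-high replicate 3 or EGFP-negative replicate 2, and without EGFP-high replicate 3 camera's adjusted p was 0.0861. Without both arrays of number 1 they came to 7. The basal genes lower came to 1 without EGFP-high replicate 2 or EGFP-high replicate 3. Single arrays ended the calls of Sfn (up to 0.0533, without EGFP-high replicate 2), Pkp1 (up to 0.126) and Pou2f3 (up to 0.0663), the last 2 highest without EGFP-high replicate 3.

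The lists for other parts of the follicle did not pass by camera with all arrays, although each held called genes; among all 5628 genes tested, 300 passed. Of 8 infundibulum and isthmus genes 2 were higher, Krt6a and the surface glycoprotein Cd200 (log2 1.57), and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.495). Of 14 sebaceous gland genes 2 were higher, the fatty acid elongase Elovl5 (log2 1.46) and the glutathione transferase Mgst1 (log2 1.92), and 0 lower (2 adjusted over the list alone; camera adjusted p = 0.13). Of 16 hair matrix and shaft genes 2 were higher and 1 lower (3 adjusted over the list alone; camera adjusted p = 0.495). The homeobox gene Dlx3 (log2 2.02) and S100a3 (log2 0.81) rose, and Gata3, a transcription factor of the inner root sheath, fell from 1893 ± 295 to 455 ± 24.7 (log2 -2.00, SE 0.16, adjusted p = 0.00026). S100a3 lost its call without 4 of the 6 arrays (adjusted p up to 0.0911, without EGFP-high replicate 3). The hair matrix and shaft genes higher came to 1 without EGFP-high replicate 2 or 3 or EGFP-negative replicate 2 or 3, and 1 sebaceous gland gene was lower without EGFP-high replicate 1. Camera's adjusted p for the sebaceous gland list was 0.0433 without EGFP-negative replicate 1. With the block 1 infundibulum and isthmus gene and 1 sebaceous gland gene were lower.

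Among the metabolism and stress lists, the ribosomal protein list passed by camera with all arrays and the filter used. Of 37 detoxification and oxidative stress genes 4 were higher and 1 lower, 6 passed when adjusted over the list alone, and camera gave an adjusted p of 0.406. Txn1, a thioredoxin (3101 ± 534 against 1087 ± 229, adjusted p = 0.00319), Ephx1 (log2 0.87), Gclm (log2 0.90) and Sod1 (log2 1.25) rose, and the metallothionein Mt2 fell (3441 ± 431 against 9148 ± 2047, log2 -1.39, SE 0.19). Of 17 glycolysis genes 0 were higher and 2 lower, the glucose transporter Slc2a1 (log2 -0.99) and the phosphofructokinase Pfkl (log2 -0.90), with 6 passing when adjusted over the list alone (camera adjusted p = 0.12, fry 0.0298). Of 22 ribosomal protein genes 0 were higher and 1 lower, Rpl13a (log2 -0.77), also when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.000712; adjusted p = 0.528 with an estimated correlation; fry 0.0655, not past the threshold). After quantile normalization that median was -0.03 (adjusted p = 0.569). By limma 0 of 33 immediate early and heat shock genes, 0 of 46 oxidative phosphorylation genes and 0 of 16 sterol synthesis genes passed, over all probe sets or over the list alone, with camera adjusted p-values of 0.495, 0.0898 and 0.393, and 4, 6 and 3 members had an unadjusted p under 0.05. Fos read 8160.4 ± 1224 against 8484 ± 2032 and Dusp1 4856 ± 979 against 6250.2 ± 2392. Atp5a1 and Cox6c, of oxidative phosphorylation, read 1906 against 2164 and 1807 against 2276, and Srebf1, of sterol synthesis, 560.1 against 778. Hmgcs1, of sterol synthesis, read 619 ± 169.6 against 1145 ± 192 and did not pass (adjusted p = 0.061), but passed with the block (0.0155), with array weights (0.0384) and without EGFP-high replicate 1 (0.0246). The block gave 4 immediate early genes higher and 4 lower, 3 oxidative phosphorylation, 6 ribosomal and 5 detoxification genes lower, and 5 glycolysis genes lower with 1 higher. Single arrays ended the calls of Ephx1 (up to 0.0785), Gclm (up to 0.153), Sod1 (up to 0.165), Slc2a1 (0.0512) and Pfkl (up to 0.174), each highest without EGFP-high replicate 3, and of Rpl13a (up to 0.16, without EGFP-high replicate 2). The detoxification genes higher came to 1 without EGFP-high replicate 2 or 3 or EGFP-negative replicate 2 or 3, and to 2 without EGFP-negative replicate 1. Those lower came to 3 without EGFP-high replicate 1, 2 without EGFP-negative replicate 1 and 4 without both arrays of number 1. The glycolysis genes lower came to 0 without EGFP-high replicate 3 and to 1 without EGFP-high replicate 2 or any 1 EGFP-negative array. Of the 3 lists with no call, the immediate early list had 1 gene past the threshold without EGFP-high replicate 1 or 3 or EGFP-negative replicate 3, and the sterol list 1 without EGFP-high replicate 1. Camera's adjusted p was 0.00386 for the immediate early list without EGFP-negative replicate 1 and 0.00484 for oxidative phosphorylation without EGFP-negative replicate 3.

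Markers of other cell types were tested as lists and singly. By camera 0 of the 7 marker lists with at least 5 tested members passed, with adjusted p-values of 0.11 for melanocytes, 0.406 for Langerhans cells and macrophages, 0.508 for leukocytes, 0.534 for fibroblasts, 0.749 for endothelial cells, 0.508 for Schwann cells and 0.798 for muscle. By fry the melanocyte list (adjusted p = 0.0373) and the Schwann list (0.0298) passed. Single members passed: Mitf of the melanocyte list (log2 1.13, 5 tested), Cd7 of the T cell list (log2 1.10, 3 tested), Col5a2 of the fibroblast list (log2 1.75, 12 tested) and Gfra1 of the Schwann list (140.1 ± 21.4 against 25.5 ± 5.35, log2 1.83, 5 tested) rose. Thy1 of the T cell and fibroblast lists (log2 -1.51), Arhgdib of the leukocyte list (log2 -0.84, 8 tested) and Bmp4 of the dermal papilla list (log2 -0.76, 4 tested) fell. Adjusted over the list alone 3 passed for Schwann cells (1 higher, 2 lower) and for fibroblasts (2 higher, 1 lower). There were 2 for T cells (1 higher, 1 lower), and 1 each for melanocytes, leukocytes and dermal papilla. None passed by limma among 10 Langerhans and macrophage, 5 endothelial, 7 muscle, 2 Merkel, 2 erythrocyte and 4 simple epithelium markers, over all probe sets or over the list alone, and 0 adipocyte markers were bright enough to test. At an unadjusted p under 0.05 these lists held 2, 1, 2, 0, 0 and 2 members in that order. Their brightest members read 319.8 against 265 for Cd14, 235 against 238 for Cd74, 232 against 306 for Eng, 82.8 against 94.3 for Sox18, 92.2 against 95.8 for Ckm, 81.8 against 81.4 for Tagln, 74.5 against 62.6 for Chga, 59.3 against 47.8 for Krt20, 179 against 142 for Hba-a1, 87.5 against 80.2 for Slc4a1 and 160.1 against 305 for Cldn4. Epcam read 259 against 173 and passed with the block only (adjusted p = 0.135, with the block 0.0463). The block also gave 2 fibroblast markers higher, and 1 each of the Langerhans and muscle lists. Single arrays ended the calls of Mitf (up to 0.0599), Cd7 (up to 0.0697), Col5a2 (up to 0.138) and Bmp4 (up to 0.0911), each highest without EGFP-high replicate 3, and of Thy1 (up to 0.119) and Arhgdib (up to 0.0806), both highest without EGFP-negative replicate 2. Without EGFP-high replicate 1, 1 endothelial, 1 muscle and 1 simple epithelium marker passed.

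**Figure D3:**
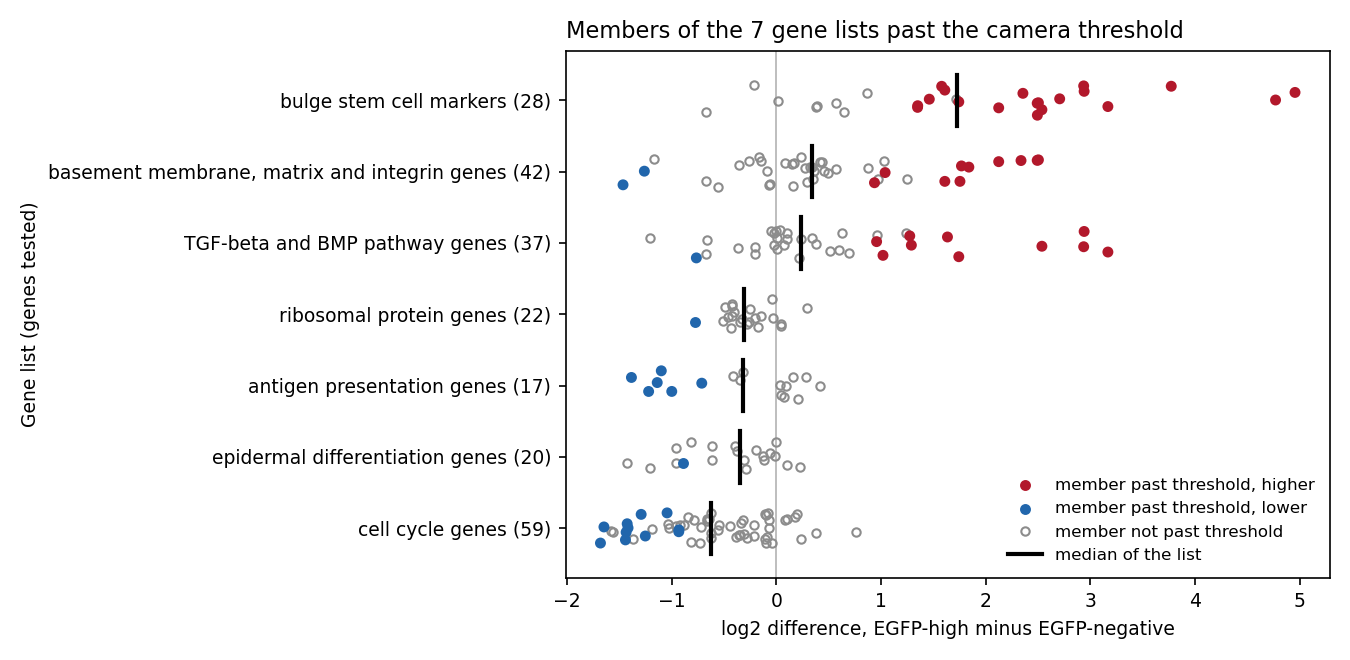
Log2 difference (EGFP-high minus EGFP-negative) of each tested member of the 7 gene lists past the camera threshold; filled points passed the threshold (red higher, blue lower), open points did not, and black bars mark the list medians. The bulge list has its median at 1.73 and the cell cycle list at -0.63, and the 4 lists with negative medians hold 0 members that passed as higher; the ribosomal median was -0.03 after quantile normalization.

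Of the 387 probe sets, 35 had no single gene symbol, and 21 of these had no listed gene. Among those 21, chosen after their values were seen as the largest rise and fall, 94122_at read 747 ± 212 in EGFP-high against 7.43 ± 2.72 in EGFP-negative (log2 4.81, SE 0.22, a size that depends on the pseudocount because the EGFP-negative values are at the level of the control probe sets) and 93078_at read 317 ± 231 against 2623 ± 101 (log2 -3.20, SE 0.40). For the 98 genes named by the rule and tested, 20 further probe sets were tested. In 3 of these the sign differed from that of the gene's brightest probe set, and 0 of the 3 passed the threshold. Pdlim1 was 1 of them, at log2 0.17 on its other probe set, and lost its call when all probe sets of a gene were averaged (adjusted p = 0.21). The other probe set of Col6a1 read 443 against 12.9, the latter at the level of the control probe sets, so its log2 difference of 3.80 depends on the pseudocount, and that of Slc6a4 had -0.41 and did not pass (adjusted p = 0.313). Of 2 further probe sets each of H2-D1 and H2-K1, 1 of each did not pass (adjusted p = 0.0581 and 0.102). The other probe sets of Cpxm2 (log2 -2.58, limma adjusted p = 0.00635), Tcf7l1 (log2 1.90, 0.00612) and Pkp1 (log2 -1.17, 0.0214) passed with the same sign. That of Tcf7l1 read 30.4 in EGFP-negative cells, so its size depends on the pseudocount. Whether these calls held without single arrays was not computed.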

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

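Leaving out both arrays of number 1, and the replicate block with an estimated correlation, were chosen after seeing the data. The 387 probe sets past the threshold became 778 with the block (382 higher, 396 lower), 191 to 500 when 1 array was left out (108 to 266 higher, 83 to 234 lower), and 2 with Welch's test, which does not share the spread among probe sets. The cause of the change with the block was not tested. Those at least 2-fold came to 182 to 385 with 1 array left out. The other alternatives gave 327 to 469 probe sets, and none of the 387 changed sign under any alternative that tested them. The stricter filter left 85 of the 387 untested.

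Camera's 7 gene lists became 0 with an estimated correlation, with or without the block, and 6 to 9 when 1 array was left out. With 4 residual degrees of freedom the estimated correlations rest on few arrays, and the cause of the loss was not tested. Fry passed 8 lists: it ended the calls of the epidermal differentiation (adjusted p = 0.197), TGF-beta and BMP (0.0655) and ribosomal lists (0.0655) and added FGF, Hedgehog and Notch, glycolysis, melanocyte and Schwann lists. The glycolysis list passed with the stricter filter (adjusted p = 0.00757). Of the 80 named genes past the threshold, 52 kept their call under every alternative in which they were tested and 67 under every one that left out no array; 0 reversed. Without a filter 11 named genes lost their call. The fits that left out arrays had no block, so they do not show how calls hold under the pairing. With the block and all arrays, limma's adjusted p was 0.000402 for Id2, 0.000462 for Anln, 0.00162 for Wnt4 and 0.00214 for Tcf7l1. It was nearer the threshold for Gclm (0.0234) and Gli2 (0.0338). The block gained Epcam and Hmgcs1, the latter gained also with array weights and without EGFP-high replicate 1, and the block changed no other call of a named gene or gene list by camera. No alternative moved the median of all probe sets by over 0.1; the largest value was -0.0238, with the stricter filter. Signal over background limits what can be read: with control probe sets at medians of 9.6 to 16.5, genes below an intensity near 44.5 were not tested.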

Other observations

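The tests of cells from the EGFP-negative gate and of endothelial cells were written before their results were seen; all other tests in this part were chosen after. All genes in this part that fall outside the naming rule were chosen after their values were seen.

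The array of EGFP-high replicate 1 lay nearer to the EGFP-negative arrays than the other 2 of its group; cells of the EGFP-negative gate in that sample would pull genes higher and genes lower in EGFP-high toward the other gate by the same share. For up to 100 genes per direction, chosen on pairs 2 and 3 alone, the median shares were 39.8% (34.5 to 48.8) for genes higher and 23.4% (14 to 31) for genes lower, a difference of 16.4 percentage points (95% bootstrap interval over genes 5.78 to 31.2), and the share for genes lower was not above the 23.7% (7.8 to 29.7) of EGFP-negative replicate 2. The prediction written beforehand for an admixture failed in both parts: the interval left out 0, and the share for genes lower was not above every other array. That interval leaves out the spread between arrays, however. EGFP-high replicate 3 had a difference of -27.8 and EGFP-negative replicate 2 of -21.5, but EGFP-high replicate 1 was part of the reference for both. These differences are therefore not independent of it, and the test cannot decide on an admixture. RNA degradation is argued against by the beta-actin 3′ to 5′ ratio of 1.418, within the range of 1.259 to 2.031 of the other arrays. An admixture, a difference between animals or sorts, and whatever set both arrays of number 1 apart stay open; the 18S ribosomal RNA control read 206.8 and 145.8 on these 2 arrays and 18.4 to 44.2 on the others.

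The probe sets of Krt15, Krt14 and Krt5 were at the level of the control probe sets, except Krt5 on EGFP-high replicate 2. Few keratinocytes among the sorted cells could produce such low values. The other 17 basal keratinocyte genes had a median percentile of mean intensity of 96.1, and 14 of them were above 80, which argues against it. Probe sets that do not detect these transcripts remain possible and were not tested, and no biological explanation was tested.

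Matrix genes and Cd34 were higher in EGFP-high cells, and fibroblasts or endothelial cells within the gate could bring both. Fibroblasts hold Col1a1 (238 against 171), Col1a2 (708 against 712.5), Col3a1 (25.8 against 21.5) and Dcn (45.4 against 54.8) in abundance. These 4 had a median log2 difference of 0.0743, where the 10 matrix genes that rose had a median of 1.8. Col3a1 was too dim to test, and Dcn lay near the level of the control probe sets. The upper limits for Col1a1 (1.08) and Col1a2 (0.357) were under 1.8. This argues against a fibroblast share large enough to raise both by that much. The level of both in EGFP-negative cells would hide a smaller share. In the fibroblast list Col5a2 rose (log2 1.75) and Thy1 fell (log2 -1.51), and a smaller share of fibroblasts stays open. Pecam1, Cdh5, Kdr and Tek had a median of 0.0742, but the upper limit for Kdr was 1.2, above the bound of 1 set beforehand, and 3 of the 4 were too dim to test, so endothelial cells cannot be told apart from a rise within keratinocytes on these values. Of the 5 tested members of the endothelial list, Eng (232 against 306, log2 -0.36, SE 0.17) and Sox18 (82.8 against 94.3, log2 -0.17) had negative differences. Their level in EGFP-negative cells would hide a small share of endothelial cells. In that list 3 of 5 differences were positive (median log2 0.148), and 1 member passed as higher without EGFP-high replicate 1. These values leave endothelial cells open. Sorting on α6 integrin does not by itself remove endothelial cells, and matrix expression by the bulge cells themselves stays open as a hypothesis.

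Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave 387 probe sets; the highest other gave 0. With 10 splits the share cannot fall under 0.05. Each other split also mixes the groups, so any difference between the groups adds to its residual spread and lowers its count. The 0 is therefore not a measure of what chance gives, and the splits cannot decide.

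The fall in cell cycle genes was larger for genes of mitosis than for genes of DNA replication. Cell phases were not measured, so this difference cannot be tied to the share of cells in either phase. The 28 genes of mitosis had a median log2 difference of -0.931 (8 lower) and the 22 of replication -0.259 (1 lower), a difference of -0.672 (two-sided permutation over genes, p = 0.00022), and of -0.777, -0.516 and -0.632 in the 3 pairs. The permutation treats genes as independent, which cell cycle genes are not. Nusap1 (95.6 against 313, log2 -1.55) and Prc1 (106 against 333, adjusted p = 0.00459), of the mitotic spindle, also fell.

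Called genes gathered in 2 families of gene symbols, of 340 tests on 170 families (12 had an unadjusted p under 0.05). A family here is a shared symbol prefix, and the Il genes are not of 1 protein family. Il genes were lower in 5 of 15 tested (Il1r2, Il12rb2, Il1rn, Il4ra and Il6st; adjusted p = 0.00505) and S100 genes higher in 4 of 8 (S100a1, S100a3, S100a4 and S100a6; adjusted p = 0.0093). Single omissions of 4 of the 6 arrays ended the calls of Il12rb2 (adjusted p up to 0.153), Il6st (up to 0.152), Il4ra (up to 0.115) and S100a3 (up to 0.0911). The call of Il1rn was ended by 5 of 6 (up to 0.0947). The adjusted p was highest without EGFP-high replicate 3, and for Il4ra without EGFP-negative replicate 2. The probe set of S100a1 is of a type that can share signal with related transcripts, so its call may not be separate from the other S100 calls. S100a4 and S100a6 were also members of the bulge list. Fisher's exact test, used for the families, counts each gene as independent.

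Several secreted factors and receptors outside the naming rule differed, and kept their calls without any single array. Bdnf read 449 against 90.7 (log2 2.14, adjusted p = 0.00147), Cxcl12 183 against 56 (log2 1.42), the semaphorin receptor Plxna2 585 against 106 (log2 2.27), Alcam 413 against 73.3 (log2 2.21) and Tnfrsf11b 488 against 64.5 (log2 2.59). The Wnt inhibitor Apcdd1 read 283 against 935 (log2 -1.66) and Tnfrsf19 41.6 against 175 (log2 -1.65).

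Nfib (1997 against 670, log2 1.51) and Bnc1 (504 against 142, log2 1.65) rose, and, also transcription factors, Foxq1 (50.1 against 250, log2 -1.96) and Ahr (197 against 492, log2 -1.23) fell, each with a call that held without any single array. Ifngr1 (105 against 357, log2 -1.59), Ifitm3 (1164 against 2830, log2 -1.27) and Ikbke (52.4 against 201, log2 -1.64) also fell; no list of interferon response genes was tested.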
